A study of Homo sapiens with 2 samples.

How the data were processed

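RNA immunoprecipitation followed by sequencing (RIP-seq) was carried out in ARP1, an established human multiple myeloma cell line. The samples were 1 library of RNA recovered with an antibody against SFRS8 (the IP library) and 1 library of input RNA without antibody. SFRS8, also named SFSWAP, is a regulator of pre-mRNA splicing. Per the labels' protocols, cell lysate was incubated with antibody-coated magnetic beads, proteins were digested, and RNA was extracted, fragmented, copied with random hexamer primers and sequenced on an Illumina HiSeq instrument. The same protocol text also describes an incubation of fragmented RNA with an antibody against m6A (N6-methyladenosine). Whether that step was applied to these libraries is unclear, so the peaks are described here as those of the labelled SFRS8 IP.

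The deposited data used were a single list of peaks, one row per peak and overlapping gene, on GRCh38. Per the submitters' processing notes, FastQC 0.11.5 and HOMER were used and the build was GRCh38. The version of HOMER, the aligner and the peak caller were not given in the sources used here. The counts in the deposited list are whole reads per peak in a test library and in a control library, without normalization. The file header does not name the libraries. The unprefixed count was read as the IP library and the count prefixed CTL as the input library, which is the usual meaning of these words but is not stated. The log-odds score of each peak and its counterpart for the control are the authors' deposited values. The p-value, the adjusted p-value and the empirical false discovery rate of each peak are also the authors' deposited values. These scores and p-values were used only to describe, rank and filter peaks within the list. Another 2 columns of values per library, named as reads per kilobase, were not used.

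The list held no library totals, so the depth of each library is unknown and IP reads were not scaled to control reads. The measure of strength was the number of IP reads per control read in a peak, called the ratio below. A ratio under 1 therefore does not mean depletion. Only the order by the ratio of peaks with control reads is independent of depth. Where a peak had 0 control reads, the ratio was computed against a floor of 3 control reads in that peak. The place of such a peak in the order depends on this floor. For the named genes among them, the lower bound of the counting interval is given as well. Ratios carry exact Clopper-Pearson 95% intervals from the split of reads between both libraries, and shares of peaks carry exact Clopper-Pearson 95% intervals. The interval of a median over peaks came from the binomial distribution of ranks. These intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Each group had 1 library, so differences between IP and input have no replicate check, no test between conditions was made and no p-value was computed across genes.

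The 279 rows were reduced to 236 distinct peaks, and a peak listed with several genes was counted once, under its protein-coding gene where there was one. Of 238 Ensembl gene identifiers, 198 had a symbol in the list. Another 22 were named by a reciprocal overlap of at least 80% with a gene of the RefSeq table for the same build, among them 1 symbol that had been turned into a calendar date (SEPTIN6), and 18 stayed unnamed. Of 193 listed symbols found in the RefSeq table, 193 overlapped the gene of that name. Reads of peaks shared by overlapping genes or by near-identical copies, such as the histone genes of chromosome 1 and the pair EIF3C and EIF3CL, cannot be assigned to one gene and are uncertain.

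Before the data were examined, 24 gene lists, the rule for named genes and most processing alternatives were fixed. The lists covered genes tied to the study, SR proteins, SR-related proteins, hnRNP proteins, core spliceosome proteins, ribosomal proteins, proteasome subunits, plasma cell identity, myeloma genes, endoplasmic reticulum (ER) and secretion, vesicle trafficking, bone factors, calcyclin-binding protein partners, m6A machinery, nuclear long non-coding RNAs, small non-coding RNAs, mitochondrially encoded genes, histones, immunoglobulins, proliferation, and markers of T cells, myeloid cells, erythroid cells and stroma. The genes named are the 10 genes with the highest ratio and the 10 genes with the most peaks among genes with a symbol in the deposited list, with ties by the larger number of peaks and then by symbol, every gene tied to the study, and the 2 members with the highest ratios of every other list. Genes named outside this rule are said to be chosen after their values were seen. The planned fold enrichment was absent from the list, so the ratio took its place. For a list with at least 3 members, the median ratio of the members' strongest peaks was placed among 10000 random lists of the same size drawn from genes with a peak and matched on the number of peaks per gene. A percentile of at most 2.5 or at least 97.5 was called. This describes the 2 libraries and is not a test of conditions. The procedure was checked on simulated counts for the 238 genes. For the 21 ribosomal protein genes, a shift by a factor of 3 was called in 62% of runs upward and 58% downward. For the 11 histone genes it was called in 46% upward and 37% downward. Without a shift, 3% of the ribosomal runs fell in the upper tail and 2% in the lower, and of the histone runs 0% and 1%. The simulated ratios were drawn independently of control reads, with no minimum of IP reads and no shared peaks, unlike those of the list. These rates therefore do not cover a relation between ratio and control reads. Simulated intervals of a ratio covered the true value in 96.5% of 2000 runs. These runs used a single true ratio, no minimum of IP reads and more expected control reads than the 10 genes with the highest ratios had. The coverage therefore does not extend to the intervals of those genes.

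The planned distances to exon boundaries and codons, and the planned sequence analysis, needed an exon annotation and a genome sequence that were not used here. In their place, the relative position of peak centres along the gene was compared with 20 random placements, for peaks centred inside a protein-coding gene and narrower than 25% of it. Relations between the score and read numbers are Spearman correlations across peaks, with intervals from 1000 resamples of peaks, and peaks are not independent replicates. The alternatives tried were a stricter adjusted p-value (the loosest divided by 10), ratios at or above the median, merging of peaks within 100 bases, other rules for gene classes and other settings of the random lists. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.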

Results

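RNA recovered with the SFRS8 antibody was compared with input RNA in ARP1 myeloma cells, using 1 IP library and 1 input library. The comparison asks which transcripts the splicing regulator SFRS8 associates with in myeloma cells and whether CACYBP, the gene of calcyclin-binding protein, is among them. The list held 236 peaks on 21 chromosomes, 105 on the plus strand and 131 on the minus strand, with a median width of 2085 bases and a range of 200 to 44640 bases. Peaks held 12068 IP reads and 87259 control reads over 952 kb in all. The median peak had 21.5 IP reads and 145 control reads, and no peak had fewer than 11 IP reads. The depth of the whole libraries is unknown, so each ratio below is the number of IP reads per control read in a peak and has meaning only against other peaks. The header does not name the libraries, and every order by ratio would turn if they were exchanged.

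The peaks lay mostly in protein-coding genes, but the ribosomal RNA (rRNA) genes took a far larger part of the IP reads in peaks than of the control reads in peaks. Shares of reads are of the 12068 IP reads and 87259 control reads in all peaks. The shares of the whole libraries are unknown. Protein-coding genes held 209 of 236 peaks (88.6%, 95% interval 83.8 to 92.3), with 72.5% of IP reads and 94.0% of control reads. rRNA genes held 4 peaks (1.69%, 0.464 to 4.28), with 21.9% of IP reads and 1.64% of control reads. Processed pseudogenes held 3 peaks, and 16 peaks (6.78%, 3.92 to 10.8) carried no gene in the list. A single peak each lay in a small nuclear RNA gene, a long intergenic RNA gene, an unprocessed pseudogene and TERC, the gene of the RNA component of telomerase. The small nuclear RNA peak lay at RNU1-3, a gene for U1, the RNA of the spliceosome that recognises 5′ splice sites. It had 13 IP and 121 control reads, a ratio of 0.107 (0.0556 to 0.191), and was chosen after its value was seen.

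The median ratio over all peaks was 0.190 (0.142 to 0.228), and the middle of the distribution ran from 0.0732 to 0.554. More IP than control reads were counted in 38 peaks (16.1%, 11.7 to 21.4), of which 15 lay in one interval of chromosome 21 and 23 elsewhere. The interval of the ratio lay wholly above 1 for 27 peaks and wholly below 1 for 180.

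**Figure D1:**
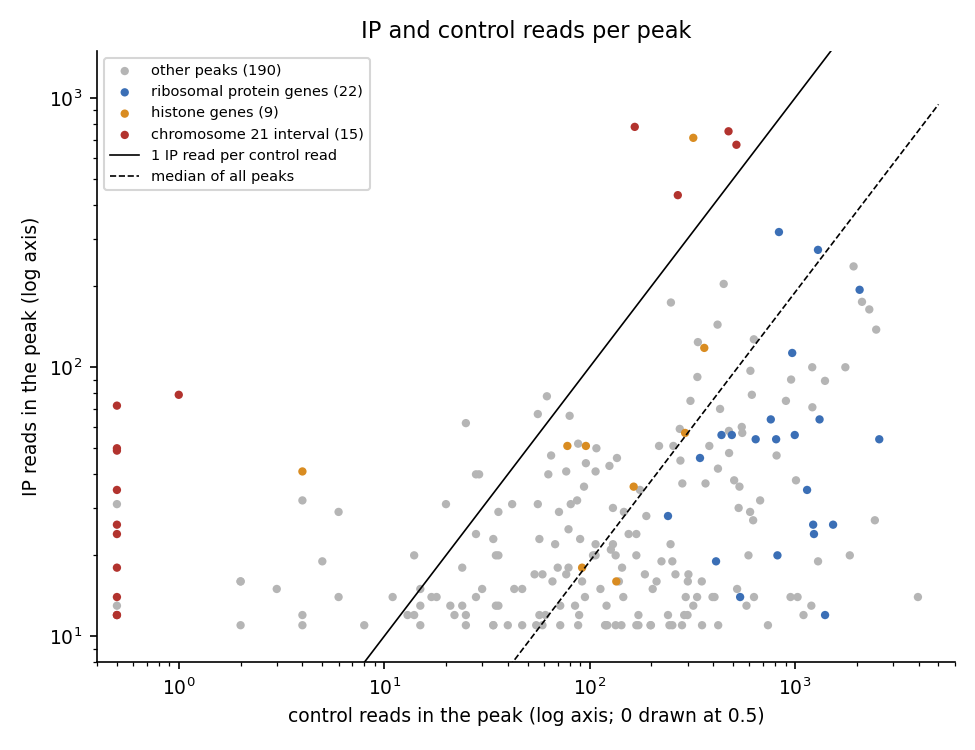
Control reads (x axis, log scale, 0 drawn at 0.5) and IP reads (y axis, log scale) of the 236 peaks, 1 point per peak, with a solid line at 1 IP read per control read and a dashed line at the median ratio of 0.190. The 22 peaks of ribosomal protein genes lie mostly under the dashed line, and the 15 peaks of the chromosome 21 interval lie above the solid line.

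An interval of chromosome 21 that holds rRNA genes had 15 peaks, all with more IP than control reads, as had 23 of the 221 peaks elsewhere. On the plus strand, 4 peaks between 8207401 and 8449400 overlapped copies of the 45S precursor and mature rRNA genes or their pseudogenes, with 2642 IP reads and 1429 control reads over 49.4 kb, a summed ratio of 1.85 (1.73 to 1.97) and a median ratio of 1.60. The highest of them, from 8434401 to 8449400 over RNA45SN1, had 782 IP and 166 control reads, a ratio of 4.71 (3.98 to 5.60), and the lowest, over RNA45SN2, had a ratio of 1.29 (1.15 to 1.45). The 221 peaks outside the interval had 9035 IP reads and 85829 control reads over 864 kb, a summed ratio of 0.105 (0.103 to 0.108) and a median ratio of 0.162. rRNA gene copies are nearly identical, so the assignment of reads to one copy is uncertain, and the interval was chosen after the values were seen.

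**Figure D2:**
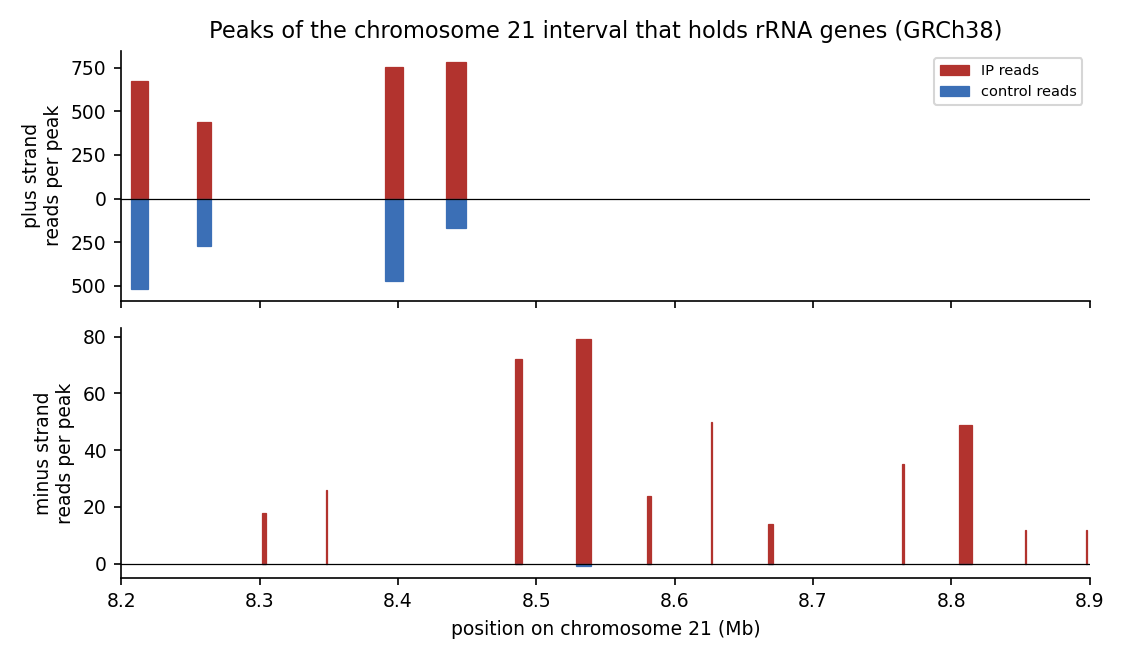
Peaks of the chromosome 21 interval that holds rRNA genes, from 8200000 to 8900000 (x axis, Mb, GRCh38), drawn to scale, with the IP reads of each peak upward and its control reads downward (y axis, reads per peak; the panels have separate scales). The 4 plus-strand peaks, over rRNA genes, hold reads of both libraries, and the 11 minus-strand peaks hold 391 IP reads and 1 control read.

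Peaks were assigned to 238 genes, 206 of them protein-coding. A single peak was listed for 218 genes, 2 peaks for 15 genes and 3 peaks for 5 genes. Among genes with a symbol in the deposited list, those with the highest ratios had few control reads. H1FX, a linker histone gene, had 41 IP and 4 control reads on chromosome 3 from 129314821 to 129315845, a ratio of 10.2 (3.71 to 39.4). A ratio of 8 was found for AFAP1L2 and ZNF598 (each 16 IP and 2 control reads, 1.88 to 71.7) and for the peak listed with ARHGAP4 (32 and 4 reads, 2.84 to 31.1). That peak had 434 of its 1200 bases in ARHGAP4, was also listed with an unnamed gene and, without regard to strand, overlapped AVPR2. ZNF598 encodes a ubiquitin ligase that senses collided ribosomes. LRRC59, which encodes a ribosome-binding protein of the ER, had 13 IP reads and 0 control reads. Its ratio was 4.33 against the floor of 3 (lower bound of the counting interval 3.05), so its rank depends on that floor. The others among these 10 were MYBBP1A, a nucleolar MYB-binding protein (5.5, 1.20 to 51.1), EIF1AX, a translation initiation factor (5, 1.41 to 26.9), SERBP1, an mRNA-binding protein (4.83, 1.97 to 14.2), TBC1D9B (3.8, 1.37 to 13.0) and SLC38A10 (3, 0.909 to 12.8). The peak of EIF1AX also overlapped SCARNA9L, a small Cajal body RNA gene, without regard to strand. TERC and the rRNA gene RNA5-8SN1 (4.71) carried no symbol in the deposited list and were not ranked with these genes, and RNA5-8SN1 was chosen after its value was seen.

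The genes with the most peaks were led by ITGB7, EIF3C, MEF2C and EEF1G, with 3 peaks each. ITGB7, the beta-7 integrin gene of plasma cells and lymphocytes, had its strongest peak on chromosome 12 from 53195301 to 53198095 with 67 IP and 56 control reads (1.20, 0.826 to 1.74). EIF3C, a subunit of translation initiation factor 3, reached 0.733 (0.305 to 1.71), in a peak with 170 of its 3780 bases in the gene. The transcription factor gene MEF2C reached 0.187 (20 IP and 107 control reads) and the elongation factor gene EEF1G 0.160 (0.128 to 0.198). Of the 15 genes with 2 peaks, the rule for ties, by symbol, named AFAP1L2, BAZ2A (0.806), BIN2 (0.5), DNAJC1 (0.338), EIF3A (0.867) and EIF3CL (0.542). Of these, EIF3A and EIF3CL belong with EIF3C to initiation factor 3, and DNAJC1 encodes a co-chaperone of the ER membrane. As the median over a gene's peaks, the ratio was 4.69 for AFAP1L2, 0.699 for ITGB7, 0.347 for EIF3CL and 0.2 for EIF3C. EIF3C and EIF3CL are near-identical, so the split of their reads is uncertain.

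Among the genes tied to the study beforehand, CACYBP had a peak, and SFSWAP, PTPRC, FN1 and MAPT had none in the list. The CACYBP (ENSG00000116161) peak ran from 175010001 to 175015500 on the plus strand of chromosome 1. It covered 1715 bases of the gene, which ends at 175011715, and its centre lay past that end. By position alone, without regard to strand, the peak also overlapped MRPS14, a mitochondrial ribosomal protein gene. The CACYBP peak had 12 IP and 241 control reads, a ratio of 0.0498 (0.0254 to 0.0886), wholly below the median of all peaks. Its IP reads lay near 11, the fewest of any listed peak. The ratio was not set against those of peaks with similar control reads, so it is not shown to be unusually low for such peaks. CACYBP was also the only gene with a peak on the list of calcyclin-binding protein partners, of 19 genes. The deposited p-value of this peak was 6.75e-16 and its score 36.1, both the authors' values.

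A small number of genes on the splicing lists had a peak. Only 206 protein-coding genes had a peak in all, and the expression of genes without a peak is unknown. A shortage of splicing genes was therefore not shown. Of 14 SR proteins, SRSF11 had a peak (0.165, 0.0989 to 0.264), and of 28 SR-related genes, SRRM2, a spliceosome scaffold protein, had one (0.242, 0.185 to 0.312). Of 22 hnRNP genes, which encode abundant pre-mRNA-binding proteins, 3 had a peak, with a median ratio of 0.0830 at percentile 27.2 of random lists. HNRNPF had 24 IP and 155 control reads (0.155) and HNRNPA1 had 75 and 904 (0.0830). None of 45 core spliceosome genes, 20 m6A machinery genes or 18 small non-coding RNA genes had a peak in the list. The U1 gene RNU1-3, whose peak is given above, was on none of these lists.

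Ribosomal protein genes formed the largest group by number, and their peaks had low ratios. Of 76 genes, 21 had a peak, and 19 of the 21 lay below the median of all peaks. The median of their strongest peaks was 0.0667, at percentile 0.82 of random lists. The highest was RPL3, with 318 IP and 836 control reads (0.380, 0.333 to 0.433), followed by RPL7A, with 273 and 1295 (0.211, 0.184 to 0.240). The peak of RPL7A had 1616 of its 12455 bases in that gene, was also listed with SURF2 and, without regard to strand, overlapped other genes. With random lists matched on control reads per kilobase the percentile was 18.7 and the call was lost. Ranked by the authors' p-values the same list lay at percentile 99.7, so its direction turned with the measure. These deposited p-values were exactly 0 for 62 peaks, most of the listed ribosomal protein genes among them, and such peaks are tied in this ranking. Of 35 proteasome genes, PSMB4 had a peak (0.148, 0.0959 to 0.221).

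Histone genes had ratios near or above the median of all peaks, with no call as a group. Of the 11 histone genes with a peak, 10 lay above the median of all peaks, and their median of 0.326 was at percentile 92.2 of random lists, short of the threshold. HIST1H1E, a replication-dependent linker histone gene, had 712 IP and 320 control reads on chromosome 6 from 26156881 to 26157390, a ratio of 2.22 (1.95 to 2.55), with 227 of the peak's 510 bases in the gene. H1FX and H1F0 are linker histone genes expressed outside of DNA replication, and without them, a choice made after their values were seen, the median of the other 9 genes was 0.220. With random lists matched on control reads per kilobase the list of 11 lay at percentile 97.8, past the threshold, whereas it lay at 83.9 with peaks centred inside the gene, 87.3 by p-value and 56.7 by the authors' score. The 11 genes shared 9 peaks, and core histone genes in the HIST2 cluster of chromosome 1 share sequence.

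Genes of plasma cells and of secretion had ratios on both sides of the median of all peaks, with more members below it than above it in each list. Of 20 plasma cell genes, 5 had a peak, with a median of 0.0821 at percentile 10.2. ITGB7 was the highest, and MZB1, an ER protein needed for antibody secretion, followed with 23 IP and 90 control reads (0.256, 0.154 to 0.408). JCHAIN, the joining chain of secreted antibodies, had 14 IP and 3971 control reads, a ratio of 0.00353 (0.00193 to 0.00592) and the lowest of all peaks, and was chosen after its value was seen. Of 35 genes of the ER and secretion, 4 had a peak, with a median of 0.122 at percentile 22.5, led by the protein disulfide isomerases P4HB (124 and 337 reads, 0.368) and PDIA3 (79 and 617 reads, 0.128). None of 26 vesicle trafficking genes and 22 bone factor genes had a peak in the list.

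Among 32 myeloma genes, 3 had a peak, with a median of 0.234 at percentile 67.0. MYC had 144 IP and 420 control reads (0.343, 0.282 to 0.415) and MAF had 51 and 218 (0.234, 0.169 to 0.319). The remaining member, CCND2, chosen after its value was seen, had 13 and 1202 (0.0108, 0.00574 to 0.0186), below the median of all peaks. Among 32 proliferation genes, 3 had a peak, with a median of 0.100 at percentile 34.6. MKI67, the gene of the Ki-67 antigen, had 204 and 450 reads (0.453, 0.382 to 0.536) and CENPF, a kinetochore protein gene, 48 and 478 (0.100, 0.0730 to 0.135). Of 20 nuclear long non-coding RNA genes, 2 had a peak. TERC had 31 IP and 0 control reads on chromosome 3 from 169764601 to 169765010. Its ratio against the floor was 10.3 (lower bound of the counting interval 7.91). SNHG3 had 35 and 176 reads (0.199, 0.134 to 0.287). No member of the lists of mitochondrially encoded genes, immunoglobulin genes, or markers of T cells, myeloid cells, erythroid cells and stroma had a peak in the list. The list held no peak on the mitochondrial sequence. A peak on chromosome 1 was listed with pseudogenes of mitochondrial genes, among them MTND1P23 and MTCO1P12. It had 14 IP and 952 control reads (0.0147, 0.00801 to 0.0248) and was chosen after its value was seen.

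**Figure D3:**
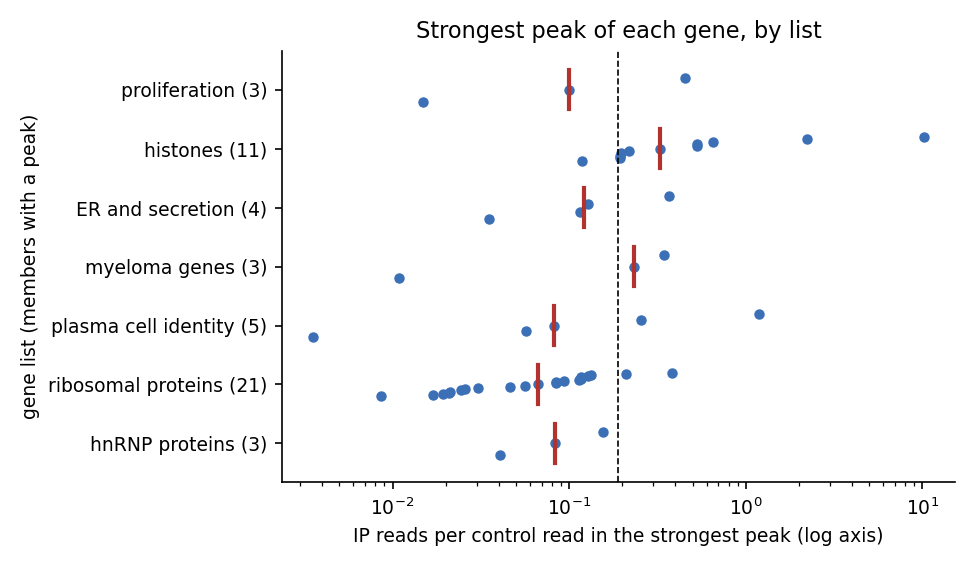
IP reads per control read in the strongest peak of each gene (x axis, log scale) for the 7 gene lists with at least 3 members (y axis, number of members in brackets), 1 point per gene, with a red bar at the list's median and a dashed line at the median of all peaks. The median of ribosomal proteins is 0.0667 and that of histones 0.326.

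Peak centres lay towards the 3′ end of genes. Of 209 protein-coding peaks, 188 were centred inside the gene, 20 past its 3′ end and 1 before its 5′ end. Among 126 peaks narrower than 25% of their gene, 82 centres (65.1%, 56.1 to 73.4) lay in the 3′-most part when the gene was split into 3 equal parts, 28 (22.2%) in the middle part and 16 (12.7%, 7.44 to 19.8) in the 5′-most part. Over 20 random placements along the same genes, 25.4% to 38.9% fell in the 3′-most part. Introns were included in the gene length, because exon positions were not used here. The strongest peaks of 6 of the 37 named genes with a peak were centred outside the gene, those of ARHGAP4, EIF3C, CACYBP, RPL7A, PSMB4 and HIST1H1E.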

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

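The tests of the chromosome 21, histone and telomerase RNA peaks were all chosen after the result was seen.

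Signal appeared in peaks without a gene in the deposited list, which the comparisons by gene did not use. Those on chromosomes other than 21 all had more control than IP reads, with ratios from 0.0390 to 0.676. On the minus strand of chromosome 21, between 8301601 and 8898000, 11 peaks held 391 IP reads and 1 control read over 38.6 kb. In 10 of the 11 peaks the control had 0 reads. The IP reads per peak ran from 12 to 79, and with the floor of 3 control reads in those 10 peaks the median ratio was 8.67. By RefSeq gene spans on either strand, the peaks starting at 8764201 and 8805801, with 35 and 49 IP reads, overlapped LINC01666. Of the 10 steps from one start to the next, 8 measured 41600 to 51200 bases and the other 2 were 96400 and 136600, a spacing like that of repeated copies. The longest step, from 8347801 to 8484401, also held the starts of the plus-strand rRNA peaks at 8390801 and 8434401. The minus-strand peaks were therefore interleaved with peaks over rRNA genes. Whether the minus-strand peaks share reads was not tested, so they are not taken as 11 separate findings.

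High ratios were seen in the 15 peaks of this interval, the TERC peak and 5 of the 9 histone peaks, but were not confined to them. Outside this part of chromosome 21, the ratio lay wholly above 1 by its interval for 12 peaks. Other protein-coding genes were among them, such as SERBP1 (4.83) and SLCO5A1 (2.48, 1.54 to 4.12), the latter chosen after its value was seen. Among the 5 histone peaks were those of H1FX and H1F0, which are not replication-dependent histone genes. The other 4 histone peaks had intervals that reached below the median of all peaks, HIST2H4A, chosen after its value was seen, being lowest at 0.119. With intervals adjusted for the choice among 236 peaks, and reads taken as independent, 15 of 15 peaks of the interval lay above that median. The lowest bound for any one peak was 0.874, though the peaks may share reads. Every listed peak had at least 11 IP reads, so a peak with 0 control reads lay above that median in any case. This held for 10 of the 15 peaks and for TERC (1 of 1, bound 2.91), where the test cannot decide. Counting error of small read numbers was argued against only at the peaks of the interval with control reads, the 4 rRNA peaks among them. For the histones as a set counting error stayed open (5 of 9). Reads copied by PCR could not be told apart, so this covers numbers of reads and not of molecules. An input library poor in RNAs without a poly(A) tail stays open for the interval, TERC and the replication-dependent histones. Of 1 peak counted at a spliceosomal RNA gene, 0 had an interval wholly below the median, which is too few to decide. A peak listed with PTMA and an unnamed small nuclear RNA gene was not counted. Its interval lay wholly below the median (0.0824, 0.0665 to 0.101), but its reads cannot be assigned to one gene. That peak was chosen after its value was seen. The tails of the minus-strand RNAs were not tested. Libraries that differ in rRNA removal alone could raise the 4 rRNA peaks but not the histone peaks, of which 5 of 9 had an interval above the median, against 86 of all 236 peaks (36.4%), which leaves this open. Binding by SFRS8 stays open and untested, because no IP with an unrelated antibody was analysed here.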

How the results depend on the processing

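Alternatives without chromosome 20, without the chromosome 21 interval, by the authors' score, on control reads per kilobase, with exchanged count columns, and those of the median ratio, of peaks with more IP reads and of peak position were chosen after seeing the data. Of 115 alternative values, 86 changed no call or stayed within the interval, or within 1.5 times, of the reported value. Keeping ratios at or above the median left 118 peaks, 114 genes and 21 listed genes, by construction. Under it, ribosomal proteins had 2 members with a peak, plasma cell genes 2, ER and secretion 1, proliferation 1, and hnRNP proteins, SR proteins, proteasome, calcyclin-binding partners and study genes 0. With peaks centred inside the gene, histones had 5 members, and proteasome, calcyclin-binding partners and study genes 0, since the CACYBP and PSMB4 peaks are centred past the gene's end. The protein-coding share was 83.1% by RefSeq gene spans at the peak centre and 94.6% without the chromosome 21 interval, which holds 15 peaks outside such genes. The percentile of ribosomal proteins turned to 99.7 by p-value and 98.9 by the authors' score, was 99.7 with the count columns exchanged (histones, uncalled, moved from 92.2 to 7.84) and was 18.7 with lists matched on control reads per kilobase; that of histones was 97.8 with this matching. The summed ratio was 0.138. Peaks with more IP than control reads numbered 23 without the chromosome 21 interval and 22 among protein-coding peaks. Except where the construction is named, the cause was not tested. Distances of 100 and 400 bases, summits, and all sequence alternatives were not run. No paired analysis was possible because each group had 1 library. The strongest ratios rest on few control reads, and whether depth limits them is unknown.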

Other observations

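The tests of exchanged columns and of score against control reads were chosen after the result was seen; those within chromosome strands and of peak position were written before their values were seen.

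The authors' deposited table placed 22 genes with a peak under the ribosome pathway, whose median ratio was 0.0614, 12 under protein processing in the ER (0.233) and 8 under RNA transport (0.637). These counts have no background and were not tested. Beyond the named genes, 19 peaks outside the chromosome 21 interval overlapped a RefSeq gene for a small nuclear or nucleolar RNA, on either strand. Their median ratio was 0.107 (0.0561 to 0.316), against 0.164 (0.131 to 0.206) for the other 202 peaks, so no difference was detectable. Their highest ratios were at EIF1AX with SCARNA9L (5) and at CHD4 with SCARNA11 (1.27), genes chosen after their values were seen.

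The authors' score fell as the ratio rose across the 236 peaks (Spearman's rho -0.49, -0.579 to -0.391). The score rose with control reads per kilobase (rho 0.783, 0.689 to 0.853), and at equal control reads the partial rho of score and ratio was 0.0807 (-0.0567 to 0.222), so the score may follow transcript abundance. An exchange of the count columns alone was argued against by 12 peaks with 0 reads in the control column, since all peaks had at least 11 reads in the other and the score was above 0 in all 236, with the control score below 0 in 228. Of these 12 peaks, 10 lay in the chromosome 21 interval and may share reads, so they are not 12 separate pieces of evidence. An exchange of the libraries before peaks were called was not tested and stays open. A separate level per chromosome strand stays open: within 11 strands of at least 10 peaks the median rho was -0.475, but 2 strands had a positive rho and the range was -0.832 to 0.412.

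On chromosome 20 all 6 scores lay between 272 and 277 although their p-values reached 0.0476, whereas the 23 other peaks with scores at least as high had p-values of 0. The percentiles by the authors' score pooled the peaks of all chromosomes despite this difference.

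For peak position, random placement along the gene was argued against by the 65.1% of centres in the 3′-most part (lower bound 56.1%, highest random share 38.9%). Long terminal exons would shift centres the same way, and this was not tested.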
